A study of Homo sapiens with 4 samples.

How the data were processed

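Extracellular RNA was sequenced from 4 lipoprotein carriers of human plasma: high-density lipoprotein (HDL), low-density lipoprotein (LDL), very-low-density lipoprotein (VLDL) and chylomicrons. Each carrier had 1 library, and the labels name the carrier of each. Per the series description, the carriers were purified by density ultracentrifugation steps and by fast protein liquid chromatography, a size-based column separation. Which of these methods was used for which library is not given in the sources used here, nor is the number of donors or whether plasma was pooled. Per the labels' protocols, RNA was extracted with miRNeasy columns and libraries were made with a NEBNext kit.

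The authors deposited 5 tables in RPM, reads scaled to library depth, for miRNAs, piRNAs, tRNAs grouped by amino acid, circular RNAs and annotated genes. The genome build was hg19, per the submitters' processing notes. The names of the deposited tables carry the name of exceRpt, a pipeline for extracellular small RNA. Its version, the aligner, the annotation release, the read filters and the reads counted in the RPM denominator are not given in the sources used here. A row of the gene table is a gene symbol with a transcript biotype, so a symbol can hold several rows.

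The most frequent value above 0 in the miRNA table, refined on whole multiples of it, was taken as the worth of 1 read in that library. It was 0.217 RPM for HDL, 9.78 for LDL, 7.35 for VLDL and 8.54 for chylomicrons. These values correspond to denominators of 4611109, 102219, 136096 and 117159 reads. Column totals of all 5 tables were whole numbers of reads within 0.01 reads. Single rows often held fractions, as when a read that maps to several features is divided between them. Together the 5 tables held 61.4% of the denominator in HDL, 60.0% in LDL, 59.0% in VLDL and 60.8% in chylomicrons. Reads outside these tables were not analysed here.

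Levels are given with exact Poisson 95% intervals, shares with exact Clopper-Pearson 95% intervals and ratios of libraries with exact conditional binomial 95% intervals, all from the read numbers above. PCR reads without molecular identifiers are not independent molecules, so intervals, floors and Monte Carlo p-values on reads cover counting error only. A level of 0 reads allows up to 3 reads, which is 0.651 RPM in HDL, 29.4 in LDL, 22.0 in VLDL and 25.6 in chylomicrons. A ratio against 0 reads was computed against that floor and is given as a lower bound. With 1 library per carrier there is no replicate check, and no p-value between carriers was computed. Monte Carlo p-values on miRNA reads compare 2 libraries and do not carry over to the carriers.

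The following choices were made before the data were examined. A feature was called led by a carrier when its log2 RPM, after adding a pseudocount, was at least 2 (4-fold) above that of each of the other 3 carriers, with at least 10 reads in the leading library. The pseudocount was the worth of 1 read in the shallowest library, 9.78 RPM. Because the minimum is counted in reads, it is 2.17 RPM in HDL, 97.8 in LDL, 73.5 in VLDL and 85.4 in chylomicrons. Named features were, per table, the 5 with the highest RPM in each carrier, the 5 led features per carrier with the widest log2 lead, and detected members of the fixed lists. Gene rows were named only where their symbol could be placed on a suitable chromosome with GENCODE release 29, which passed over 11 rows. That release is on another build than the files and served for names and transcript lengths only.

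There were 30 lists fixed in advance: 12 of miRNAs, 17 of genes and 1 of tRNAs. For each list, the median over members of the log2 difference between a carrier and the mean of the other 3 was computed. It was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. Percentiles under 2.5 or over 97.5 are reported as outside the random lists, as a description of these libraries. They are not corrected for the number of lists and carriers. Lists were also compared by their total RPM. A miRNA is called higher or lower in HDL where the interval of its ratio excludes 1. Similarity of libraries was described with Spearman correlations across features, and features are not independent replicates.

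Alternatives were 5 times the pseudocount, 5 times the minimum or none, a 2-fold lead, median-of-ratios scaling, and the gene shares with other row filters. Further alternatives were chosen after the data were seen. They were one common RPM minimum, one row per gene symbol, leaving out the LDL library, and ratios after scaling. Intervals of scaled ratios treat the scaling factors as fixed and leave out their error, so they are too narrow. The calling rule was tested on simulated reads drawn at the 4 depths. Changes were planted only in rows with a mean of at least 20 RPM, so recovery below that level is not known. Among simulated genes the rule recovered 57 of 68 changed 8-fold, 68 of 68 changed 16-fold and 64 of 64 changed 32-fold. Among simulated miRNAs it recovered 7 of 7, 4 of 4 and 4 of 4 at the same folds. It called 0 of the unchanged features in either table. In a separate check at equal depth, the ratio interval held the simulated ratio in 96.1% of 2000 draws. That check did not cover unequal depths, single reads or fractional reads. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.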

Results

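Plasma lipoproteins are particles of lipid and protein that carry fat and cholesterol in blood, and they also hold small amounts of RNA. The series profiled this RNA in 4 carriers, with 1 library each: HDL, LDL, VLDL, which the liver secretes, and chylomicrons, which carry dietary fat from the intestine. The design asks which RNAs each carrier holds. Depth differed widely between the libraries. The HDL library was 45.1 times deeper than LDL, 33.9 times deeper than VLDL and 39.4 times deeper than chylomicrons. Values in HDL are therefore far more precise than elsewhere, and single low values in the other 3 libraries rest on few reads.

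miRNAs made up a larger part of the HDL library than of any other. They totalled 11093 RPM in HDL (95% interval 10997 to 11189), 2441 in chylomicrons (2166 to 2741), 1749 in VLDL (1534 to 1986) and 577 in LDL (439 to 745). The total in HDL was 4.54 times that in chylomicrons (4.05 to 5.12), 6.34 times that in VLDL (5.59 to 7.24) and 19.2 times that in LDL (14.9 to 25.3). Y RNAs, short noncoding RNAs bound by the Ro60 protein, had the same order of carriers with other gaps. The Y RNA rows with their pseudogenes summed to 21450 RPM in HDL and 19978 in chylomicrons, against 7055 in VLDL and 2468 in LDL. tRNA reads totalled 27087 RPM in HDL, 20324 in VLDL, 17105 in chylomicrons and 14743 in LDL. piRNA totals were close to each other, between 4034 RPM in VLDL and 5068 in HDL. Annotated gene rows held 57.0% of the denominator in HDL, 58.0% in LDL, 56.3% in VLDL and 58.4% in chylomicrons.

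**Figure D1:**
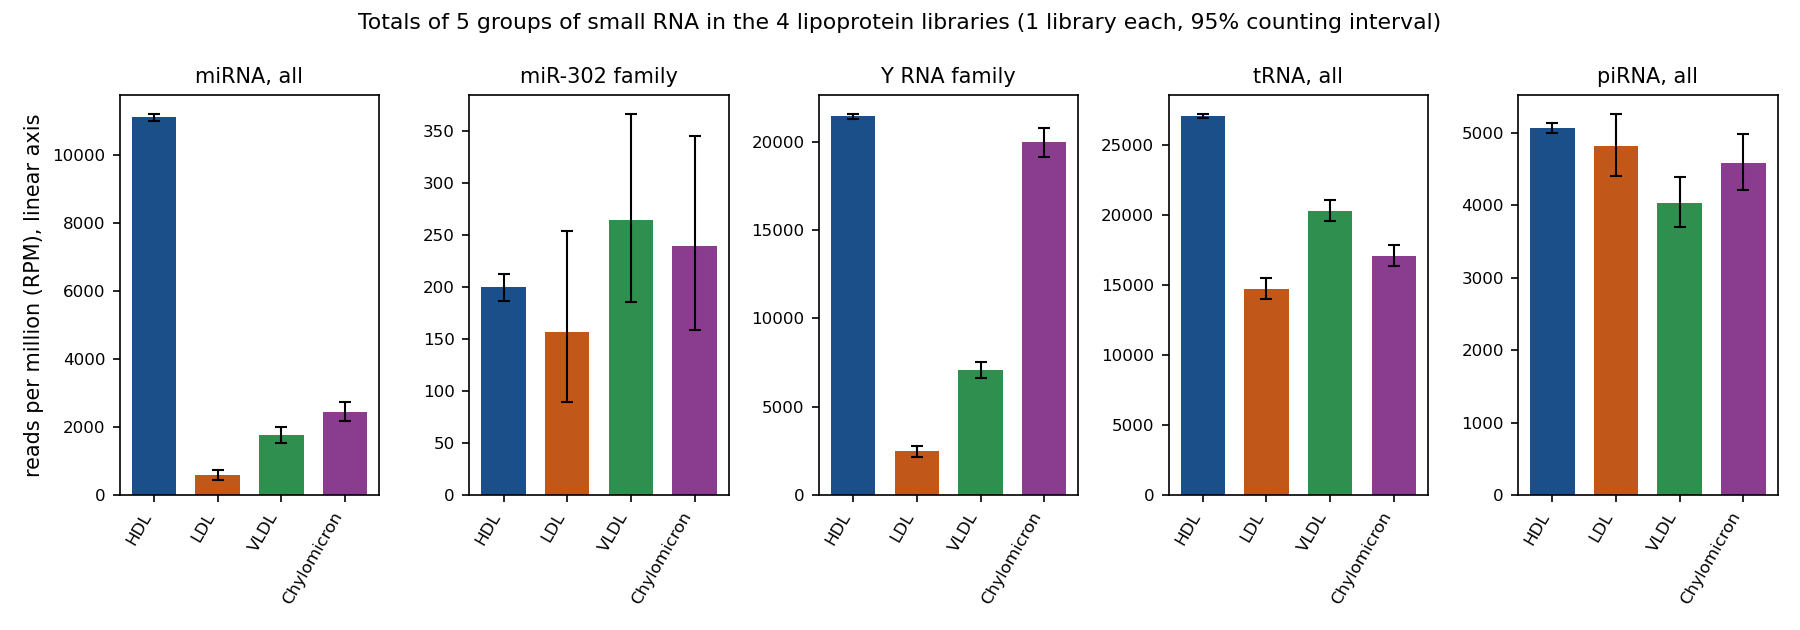
Bars give the summed level of miRNAs, the miR-302 family, Y RNAs, tRNAs and piRNAs in RPM (linear axis) in each of the 4 libraries, and error bars give 95% counting intervals. The miRNA bar of HDL stands at 11093 RPM against 577 in LDL, while the Y RNA bars of HDL and chylomicrons stand at 21450 and 19978 RPM.

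By the 4-fold rule 21 miRNAs were led by HDL, and they held 69.2% of its miRNA RPM. In 20 of the 21 the interval of every ratio also lay above 1. The most abundant was miR-126-3p, a miRNA of endothelial cells and platelets, at 1792 RPM in HDL (1753 to 1831). It was 23.3 times the chylomicron level (12.3 to 51.0), 244 times the VLDL level (43.8 to 9633, on 1 VLDL read) and at least 61.1-fold higher than in LDL. miR-10b-5p reached 941 RPM in HDL and was 36.8 times the chylomicron level (12.6 to 178) and at least 32.1-fold higher than in LDL. miR-10a-5p stood at 450 RPM in HDL, against 34.1 in chylomicrons, 29.4 in VLDL and 0 in LDL. miR-26a-5p stood at 1216 RPM in HDL and was 10.2 times the chylomicron level (6.06 to 18.6) and 55.2 times the VLDL level (18.9 to 268). miR-27a-3p and miR-27b-3p were read only in HDL, at 97.6 and 88.0 RPM, and were at least 3.81-fold and 3.44-fold higher there than in chylomicrons.

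Of the 358 miRNAs in the table, 30 were higher in HDL than in chylomicrons and 2 were lower. Against VLDL the numbers were 37 and 1, and against LDL 31 and 2. For each of the remaining miRNAs the interval of the ratio held 1 at this depth, or neither library of the pair read it and no ratio was formed. The miRNAs lower in HDL were hsa-miR-100-5p against VLDL, hsa-miR-302d-3p and hsa-miR-935 against chylomicrons, and hsa-miR-1246 and hsa-miR-518b against LDL. Of these, miR-935, miR-1246 and miR-518b rested on 1 or 2 reads and were named after their values were seen. Median-of-ratios scaling, based on 20 miRNAs read in all 4 libraries, moved the median miRNA of HDL by -0.62 on the log2 scale. Its size factors were 2.84 for HDL, 0.507 for LDL, 0.786 for VLDL and 1.30 for chylomicrons. After it, HDL led 6 miRNAs in place of 21 (12 with one RPM minimum for all libraries). Its miRNA total was then 2.09 times that of chylomicrons, 1.76 times VLDL and 3.44 times LDL. The factors come from miRNAs themselves and remove a difference that these miRNAs share. The scaled totals therefore do not test the HDL excess in RPM. The 20 miRNAs also had to be read in LDL, where 59 reads fell on 30 miRNAs. This selection by detection can bias the factors and was not corrected.

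No miRNA list lay above the random lists in HDL, although 5 times the pseudocount put the let-7 family at percentile 98.2 and lipid metabolism miRNAs at 98.1. The random lists were matched on a mean level to which HDL contributed most. Their own median log2 difference in HDL was therefore high, at 1.59 for the lists matched to let-7. Median differences in HDL lay at percentile 88.6 for platelet miRNAs, 80.2 for endothelial, 94 for let-7, 91.2 for miR-30 and 92 for lipid metabolism miRNAs. Platelet miRNAs totalled 3620 RPM in HDL, which was 10.1 times their total in chylomicrons (7.47 to 14.0), 32.8 times VLDL (19.9 to 58.7) and 92.5 times LDL (36.1 to 340). This list includes miR-126-3p and miR-26a-5p, and 5 of its 13 measured members were higher in HDL than in chylomicrons. Endothelial miRNAs, which share miR-126-3p with that list, totalled 3598 RPM in HDL and 265 in chylomicrons, a ratio of 13.6 (9.58 to 20.02). Their median log2 difference was -1.98 in LDL (percentile 0.7) and -0.32 in chylomicrons (percentile 2.2, and 12.9 after scaling). Members of the let-7 family totalled 2253 RPM in HDL and 495 in chylomicrons, a ratio of 4.55 (3.52 to 5.997), and 6 of 10 were higher in HDL. The most abundant let-7 members were let-7a-5p at 640 RPM and let-7f-5p at 541 in HDL, against 120 and 102 in chylomicrons.

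Liver miRNAs totalled 809 RPM in HDL and 248 in chylomicrons, 140 in VLDL and 78.3 in LDL. Their main members differed: hsa-miR-122-5p, the most abundant miRNA of hepatocytes, was 11.7 times higher in HDL than in chylomicrons (4.56 to 42.9), and miR-148a-3p only 1.71 times (1.14 to 2.71). The ratio of miR-148a-3p turned to 0.787 after median-of-ratios scaling (0.5225 to 1.25), and its ratio to VLDL went from 2.55 (1.61 to 4.31) to 0.705 (0.4445 to 1.19). Both scaled intervals held 1. Lipid metabolism miRNAs, which include miR-122-5p, miR-27a-3p and miR-148a-3p, totalled 1580 RPM in HDL and 452.4 in chylomicrons, with 7 of 12 members higher in HDL. Members of the miR-30 family totalled 318 RPM in HDL and 51.2 in chylomicrons, a ratio of 6.20 (2.84 to 16.9). Those of the miR-17-92 and paralogous clusters totalled 301.9 and 120 RPM, a ratio of 2.53 (1.501 to 4.63) that was 1.16 after scaling (0.689 to 2.13). After scaling the intervals of their ratios to VLDL and LDL held 1 as well.

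Red blood cell miRNAs totalled 610 RPM in HDL and 427 in chylomicrons, a ratio of 1.43 (1.08 to 1.93) that turned to 0.656 after median-of-ratios scaling (0.496 to 0.886). Within this list miR-486-5p was the most abundant miRNA of the chylomicron library at 248 RPM, against 198 in HDL. The ratio of chylomicrons to HDL held 1 in its interval (0.832 to 1.81), but after scaling HDL stood at 0.367 times chylomicrons (0.254 to 0.552). In VLDL and LDL miR-486-5p stood at 44.1 and 9.78 RPM. Myeloid cell miRNAs totalled 539 RPM in HDL and 145 in chylomicrons, a ratio of 3.71 (2.31 to 6.39) that was 1.71 after scaling (1.06 to 2.93). Lymphocyte miRNAs totalled 198 and 93.9 RPM, a ratio of 2.11 (1.18 to 4.25) that became 0.970 after scaling (0.540 to 1.95). None of the 10 was read in LDL (median log2 difference -0.84, percentile 0.8). They held 915 of 51150 miRNA reads in HDL, so at the same share few or none would be expected among the 59 of LDL. The interval of the HDL to LDL ratio started at 5.49 before scaling and at 0.981 after. Muscle miRNAs totalled 20.8 RPM in HDL and 39.1 in LDL, on 4 LDL reads, a ratio of 0.531 (0.201 to 1.99) that was 0.09495 after scaling (0.0359 to 0.356). Their median log2 difference was 0.40 in LDL (percentile 99.1) and 0.07 in HDL (percentile 0.7), and the HDL value turned to -0.39 after scaling. Intestinal epithelial miRNAs totalled 29.5 RPM in HDL, mostly miR-192-5p, with 9.78 in LDL and 0 in chylomicrons and VLDL. The chylomicron floor of 25.6 RPM lies close to the HDL level, so a lower level in chylomicrons could not be shown at this depth.

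**Figure D2:**
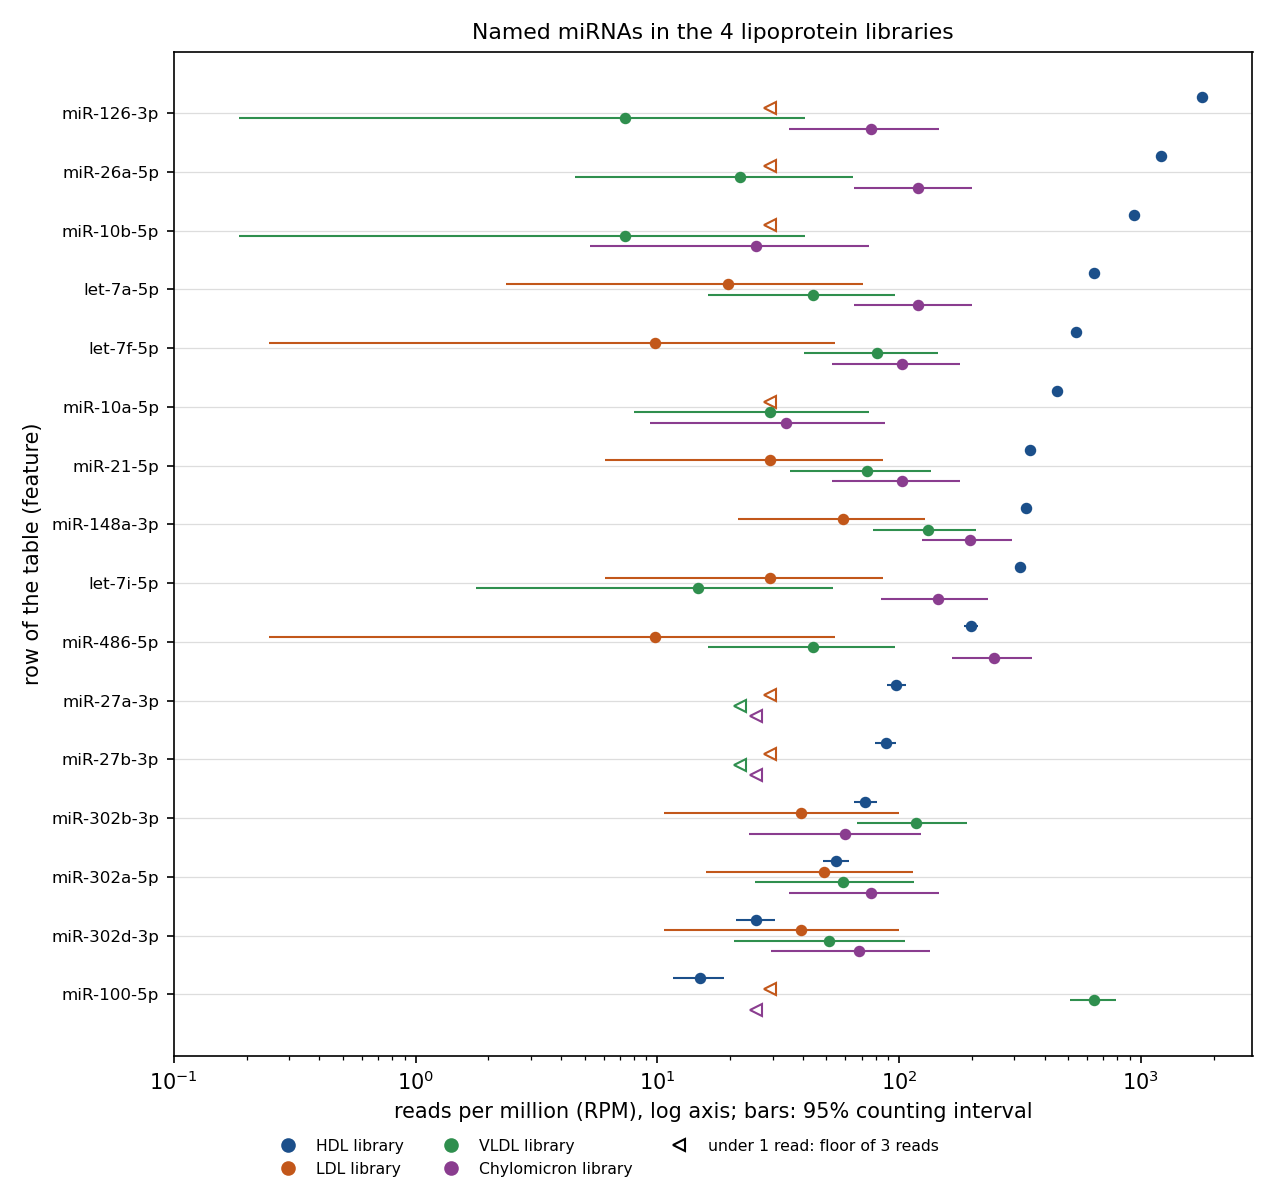
Points give the level of each named miRNA in RPM (log axis) in each of the 4 libraries, bars give 95% counting intervals, and open triangles mark the floor of 3 reads where a library had under 1 read. miR-126-3p lies at 1792 RPM in HDL, and miR-100-5p at 639 RPM in VLDL against 15.0 in HDL.

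VLDL led a single miRNA, hsa-miR-100-5p, an abundant miRNA of endothelial and other cells. It stood at 639 RPM in VLDL (512 to 789, 87 reads), which was 36.5% of the miRNA RPM of that library. The VLDL level was 42.7 times that in HDL (30.8 to 59.5), at least 25.0-fold higher than in chylomicrons and at least 21.8-fold higher than in LDL. It made up most of the 727 RPM of endothelial miRNAs in VLDL, and without it that total was 88.2 RPM, 0.0246 times HDL (0.0127 to 0.0430). hsa-miR-99a-5p, which has a closely related sequence, was not read in VLDL and stood at 108 RPM in HDL. LDL and chylomicrons led 0 miRNAs, and in LDL 0 miRNAs reached the minimum of 10 reads. The most abundant miRNA of LDL was miR-148a-3p at 58.7 RPM (21.5 to 128, 6 reads).

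tRNA reads were dominated by alanine, glycine and glutamate tRNAs in all 4 libraries. Alanine tRNA reads stood at 11440.0 RPM in HDL and between 5239 and 5378 in the other 3, and the HDL level was 2.18 times LDL (2.01 to 2.38), 2.16 times VLDL and 2.13 times chylomicrons. They were 42.2% of tRNA reads in HDL (42.0 to 42.5) and 26.1% in VLDL (24.5 to 27.8). Glutamate tRNA reads were low in LDL, at 953 RPM against 4860 in HDL, 4074 in VLDL and 3119 in chylomicrons. The ratio of HDL to LDL was 5.10 (4.18 to 6.29). Glycine tRNA reads, at 4276 to 5103 RPM, differed little. Glutamine tRNA reads were highest in VLDL at 779 RPM and lowest in chylomicrons at 155, a ratio of 5.04 (3.04 to 8.81). The list of glycine, glutamate, lysine, valine and histidine tRNAs totalled 12067 RPM in HDL, 10523 in VLDL, 8646 in chylomicrons and 6573 in LDL. No tRNA met the 4-fold rule in any carrier.

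**Figure D3:**
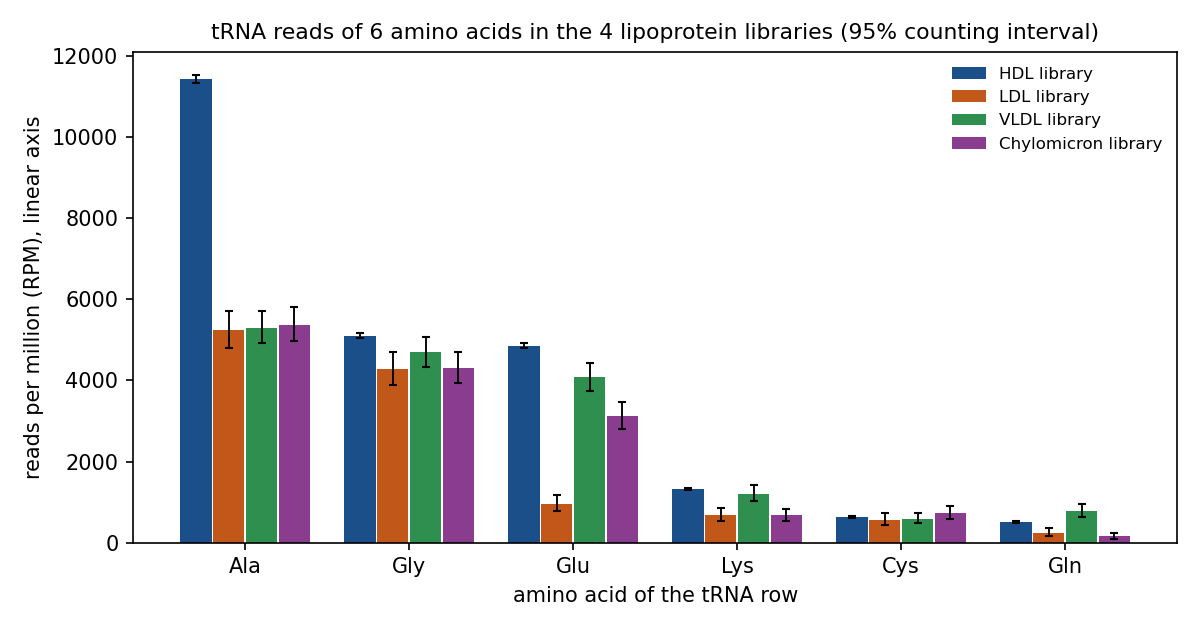
Bars give the RPM (linear axis) of tRNA reads for 6 amino acids in each of the 4 libraries, with 95% counting intervals. Alanine reads of HDL stand at 11440.0 RPM, and glutamate reads of LDL at 953 RPM against 3119 to 4860 in the others.

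Y RNAs stood furthest apart among the gene lists. The median log2 difference of the 5 members was 1.32 in HDL and 1.24 in chylomicrons (both at percentile 99.9), -0.32 in VLDL and -2.08 in LDL (percentile 0). RNY4 stood at 5431 RPM in HDL, 4993 in chylomicrons, 1532 in VLDL and 426 in LDL, and its HDL level was 12.8 times that in LDL (9.48 to 17.6). RNY1 differed less, at 470 RPM in HDL and 220 in LDL. RNY4 shares reads with its pseudogenes RNY4P10 and RNY4P7, whose levels of 5412 and 4060 RPM in HDL followed it. Summed over all Y RNA rows, where a divided read counts once, the HDL level was 8.69 times LDL (7.68 to 9.87), 3.04 times VLDL (2.85 to 3.24) and 1.07 times chylomicrons (1.03 to 1.12).

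Other noncoding lists held few reads. Mitochondrial tRNAs totalled 104 RPM in HDL, 77.8 in chylomicrons, 40.3 in LDL and 17.1 in VLDL. HDL was 6.08 times VLDL (1.82 to 40.2). Their median log2 difference was 0.24 in HDL (percentile 100), -0.10 in LDL (percentile 0.5) and -0.10 in VLDL (percentile 0.2). Mitochondrially encoded genes, mostly the ribosomal RNAs MT-RNR1 and MT-RNR2, totalled 123 RPM in HDL, 144 in chylomicrons and 57.9 in VLDL. Spliceosomal snRNAs totalled 163 RPM in VLDL and 109 in HDL, a difference within the interval of the ratio. Their median log2 difference was small, at 0.035 in VLDL (percentile 99.6) and -0.072 in chylomicrons (percentile 1.7). The signal recognition particle, vault and other Pol III RNAs totalled 45.4 RPM in HDL and 84.6 in VLDL, and again the interval of the ratio held 1. Abundant nuclear long noncoding RNAs totalled 756 RPM in chylomicrons and 502 in HDL, a ratio of HDL to chylomicrons of 0.663 (0.536 to 0.829), and their highest member in chylomicrons was KCNQ1OT1 at 275 RPM.

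Protein-coding rows held 53.9% of gene RPM in HDL, 55.8% in LDL, 55.4% in VLDL and 54.7% in chylomicrons. Retained introns held 11.2% to 11.9%, and misc_RNA rows, mostly Y RNAs, ranged from 0.546% in LDL to 3.87% in HDL. The highest gene row was the same in every library, a ZNF570 transcript annotated for nonsense-mediated decay, at 7036 to 10420 RPM. By the 4-fold rule HDL led 50 gene rows, chylomicrons 60, VLDL 48 and LDL 19. These counts do not rank the carriers, since the minimum was 2.17 RPM in HDL and 73.5 to 97.8 elsewhere. With one RPM minimum for all libraries HDL led 28, and with 5 times the pseudocount HDL led 6, chylomicrons 19, VLDL 17 and LDL 9. In the main counts, led rows held 1.46% of gene RPM in HDL, 2.67% in chylomicrons, 3.57% in VLDL and 0.879% in LDL.

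Among rows led by chylomicrons, COQ10A, which binds coenzyme Q in mitochondria, stood at 1296 RPM and 109 times its HDL level (79.5 to 151). SHC1, an adaptor of receptor tyrosine kinases, stood at 662 RPM (113 times HDL, 72.3 to 183), and SOCS3, an inhibitor of cytokine signalling, at 619 RPM (338 times HDL, 166 to 794). VLDL led ABCG1, a transporter that exports cholesterol to HDL, whose protein-coding row stood at 781 RPM and 20.5 times HDL (15.9 to 26.2). It also led ZMIZ1, a transcriptional coactivator, at 794 RPM, and RABEP1, an effector of endosome fusion, at 423 RPM. ADAM12, a metalloprotease, reached 4809 RPM in VLDL, 6.28 times HDL (5.77 to 6.83) and 137 times chylomicrons (54.0 to 494). In LDL the widest leads were in 3 rows of the TMEM256-PLSCR3 readthrough gene, of which the protein-coding row stood at 1306 RPM and 208 times HDL (139 to 323). Rows of one symbol can share reads. HDL led BLOC1S2 at 351 RPM and IL19, an interleukin of the IL-10 family, at 146 RPM.

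**Figure D4:**
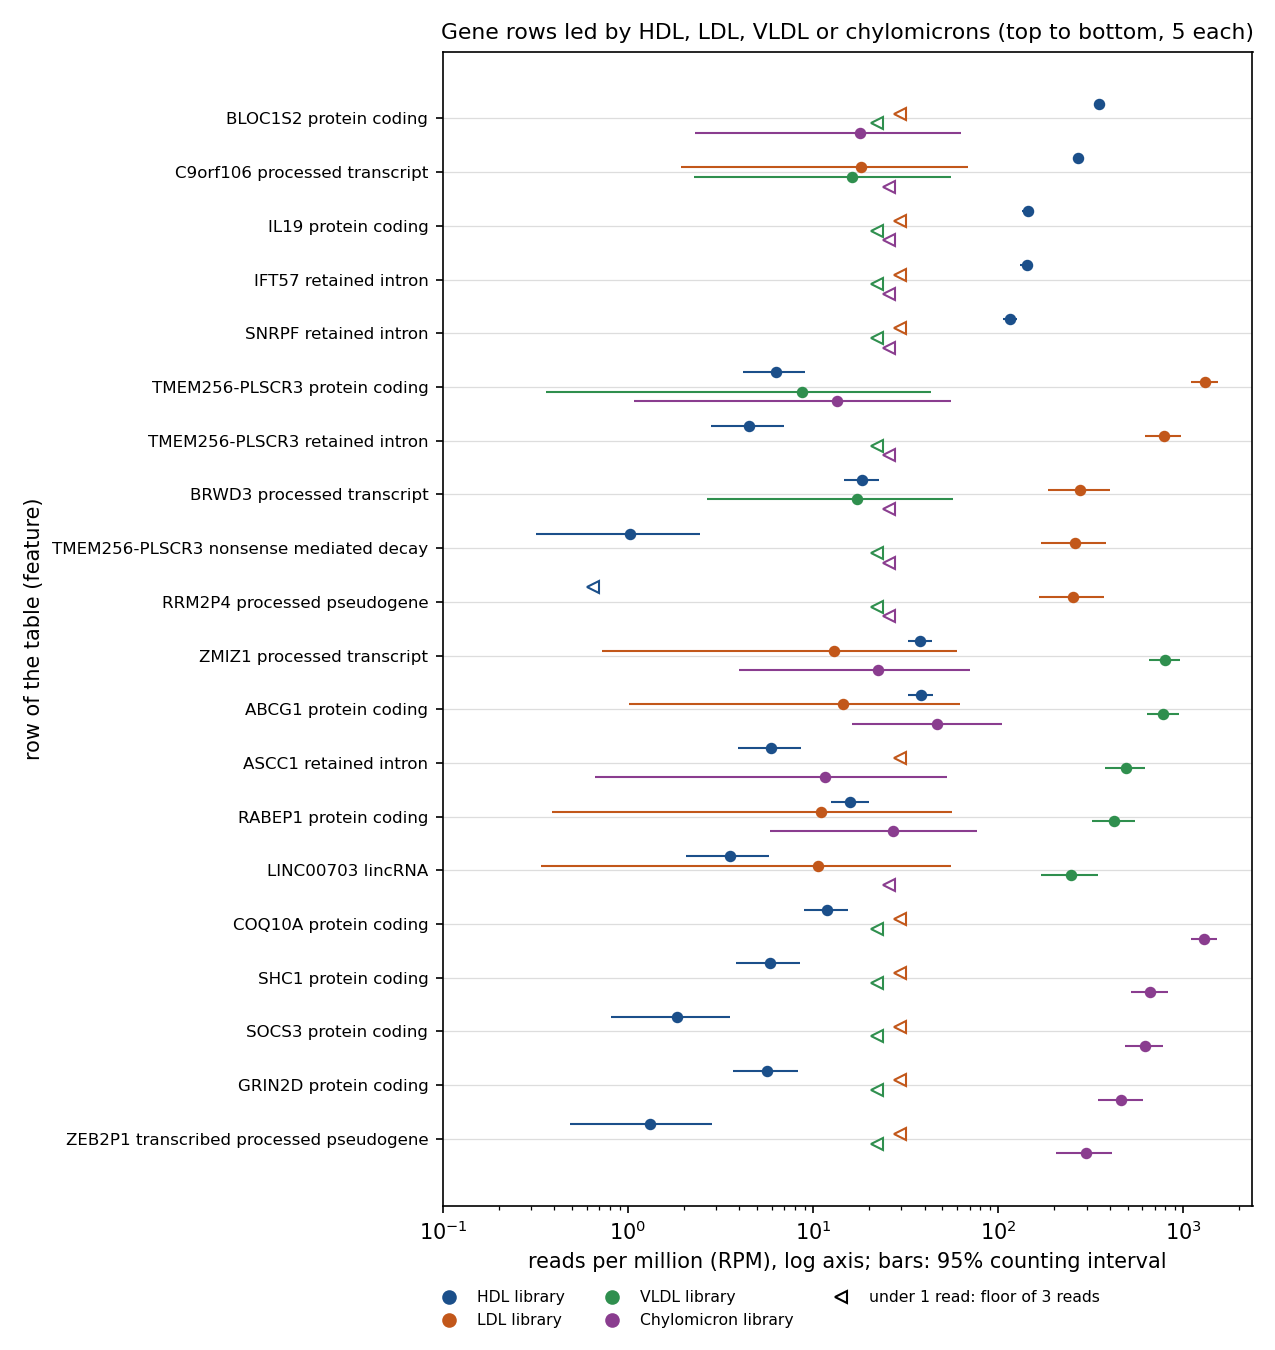
Points give the level in RPM (log axis) of the 5 gene rows led most widely by each carrier, in all 4 libraries, with 95% counting intervals and open triangles at the floor of 3 reads where a library had under 1 read. COQ10A lies at 1296 RPM in chylomicrons and 11.9 in HDL, and BLOC1S2 at 351 RPM in HDL.

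Hemoglobin and red cell genes totalled 172 RPM in HDL, 162 in chylomicrons, 129 in LDL and 122 in VLDL, and HBB itself stood at 2.85 RPM in HDL. Platelet genes totalled 207 to 247 RPM, lymphocyte genes 130 to 191, skin keratinocyte genes 198 to 283 and the adipocyte and endothelial genes 485 to 601. For each of these lists the interval of every ratio to HDL held 1. Neutrophil and monocyte genes, of which SOD2 held the most reads, totalled 386 RPM in VLDL and 479 in HDL. Their median log2 difference was -0.49 in VLDL (percentile 0), although the ratio of totals held 1 in its interval. The percentile was 98.2 for skin keratinocyte genes in chylomicrons (median log2 difference 0.25) and 98.5 for replication-dependent histone genes there (0.065). Histone totals were 58.8 RPM in chylomicrons, on 6.89 reads, and 32.7 in HDL. Enterocyte genes totalled 336 RPM in LDL, 326 in chylomicrons, 248 in HDL and 210 in VLDL. Their highest member in LDL was CREB3L3, a transcription factor of liver and intestine, at 128 RPM.

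Liver secreted protein genes totalled 564 RPM in VLDL, 356 in HDL, 267 in LDL and 259 in chylomicrons. ALB, which encodes albumin, stood at 249 RPM in VLDL and 8.72 times HDL (5.79 to 12.8), and without ALB the list total in VLDL was 0.961 times HDL (0.692 to 1.30). The median difference of the list in VLDL lay at percentile 97, at 97.7 after scaling and at 84.1 with 5 times the pseudocount. Lipoprotein receptors and lipid metabolism genes totalled 1955 RPM in VLDL, with the list median at percentile 96.3, and 883 to 969 in the others. ABCG1, summed over its rows, was 1044 RPM of this, and without it VLDL stood at 1.14 times HDL (0.946 to 1.37). Cytosolic ribosomal protein genes totalled 3302 RPM in chylomicrons, 1429 in VLDL, 1257 in LDL and 1155 in HDL. RPL12 alone was 2105 RPM in chylomicrons, and without it the ratio of chylomicrons to HDL was 1.05 (0.879 to 1.24).

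HDL led 2 piRNAs and chylomicrons 1. hsa_piR_004417 stood at 617 RPM in HDL, 63.1 times LDL (11.3 to 2492, on 1 LDL read) and at least 24.1-fold higher than in chylomicrons. hsa_piR_015682 stood at 95.9 RPM in HDL and was not read elsewhere. hsa_piR_016081 stood at 137 RPM in chylomicrons, 16.1 times HDL (8.42 to 29.6). Circular RNAs totalled 238 RPM in HDL, 230.5 in chylomicrons, 97.8 in LDL and 95.5 in VLDL, on 10 to 27 reads outside HDL. Outside LDL most of these reads belonged to hsa_circ_001712, at 189 RPM in HDL, 179 in chylomicrons, 51.4 in VLDL and 29.4 in LDL. Its HDL level was 1.05 times chylomicrons (0.685 to 1.71) and 3.67 times VLDL (1.78 to 9.16).

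Across 30099 gene rows that reached the minimum in at least 1 library, the Spearman correlation was 0.657 to 0.669 between HDL and each other library. Among the other 3 it was 0.573 to 0.577. In HDL 30068 gene rows reached the minimum, against 759 in LDL, 1096 in VLDL and 887 in chylomicrons. No value for counting noise was computed for genes, so the lower correlations among the other 3 cannot be told apart from an effect of depth. Across 126 miRNAs, all of which reached the minimum in HDL, the correlation was 0.649 for HDL and chylomicrons, 0.6004 for HDL and VLDL, and 0.357 for HDL and LDL. Identical miRNA profiles, drawn at the same denominators with the mean level of each miRNA in every library, gave 0.801, 0.808 and 0.787 for these pairs. These draws give LDL, VLDL and chylomicrons more miRNA reads than they had. The simulated values are therefore too high as a reference, and the gap to them is not interpreted. These correlations are across features within a pair of libraries and have no replicate check.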

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

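The common minimum, one row per symbol, leaving out LDL, and ratios after scaling were chosen only after the results were seen. No paired analysis was possible because each carrier had 1 library. Depth limits all values outside HDL, whose minimum of 10 reads is a much lower RPM. With 5 times the pseudocount HDL led 6 miRNAs, 6 genes and 1 piRNA, LDL 9 genes, VLDL 17 genes, and chylomicrons 19 genes and 0 piRNAs. With 5 times the minimum LDL led 2 genes, VLDL 11, and chylomicrons 6 genes and 0 piRNAs. With no minimum LDL led 64 genes and 2 piRNAs, VLDL 73 and 2, and chylomicrons 93 and 3. At 2-fold HDL led 45 miRNAs, 255 genes and 7 piRNAs, LDL 38 genes, VLDL 130 and chylomicrons 111. With the common minimum HDL led 12 miRNAs, 28 genes and 1 piRNA. The 4 gene counts redone with one row per symbol, and the 9 counts redone without LDL, stayed within 1.5 times their values.

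After scaling, HDL led 6 miRNAs, and its miRNA total was 3.44 times LDL, 1.76 times VLDL and 2.09 times chylomicrons. Some ratios of HDL to another carrier excluded 1 in their unscaled interval and lay below 1 only after scaling. They were red blood cell miRNAs (0.656) and lymphocyte miRNAs (0.970) against chylomicrons, and miR-148a-3p against VLDL (0.705) and chylomicrons (0.787). After scaling, only the interval of red blood cell miRNAs among these excluded 1. The median log2 difference of muscle miRNAs in HDL turned to -0.39. Intervals after scaling leave out the error of the size factors, which limits the following counts. Of 36 ratios of miRNA lists, 31 lay above 1 with their interval before scaling and 21 after, and those below 1 went from 0 to 2. Of 48 ratios of named miRNAs, those above 1 went from 35 to 21 and those below from 2 to 9. The cause was not tested. HDL had 4 lists above the random lists with 5 times the pseudocount, and VLDL 2 after scaling.

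Gene correlations with 5 times the minimum were 0.622 (HDL and LDL), 0.625 (HDL and VLDL), 0.601 (HDL and chylomicrons), 0.592 (LDL and VLDL), 0.595 (LDL and chylomicrons) and 0.583 (VLDL and chylomicrons). With no minimum they were 0.704, 0.723, 0.710, 0.621, 0.614 and 0.620, in that order. Protein-coding shares without the 10 highest rows were 55.8% in HDL, 56.0% in VLDL and 56.6% in chylomicrons. Over rows at the minimum they were 55.7% in HDL, 58.8% in LDL, 58.5% in VLDL and 57.5% in chylomicrons.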

Other observations

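The tests on dilution and on Y RNA reads were chosen only after the results were seen, while those on depth and on mRNA fragments were planned. The miR-302 family, known from pluripotent stem cells, did not share the HDL excess of other miRNAs in RPM, and was lower in HDL after median-of-ratios scaling. Its 6 mature forms summed to 200 RPM in HDL (187 to 213), 156 in LDL (89.5 to 254), 264 in VLDL (185 to 366) and 239 in chylomicrons (159 to 345), and each ratio to HDL held 1 in its interval. After scaling the sum in HDL was 0.228 times LDL (0.140 to 0.401), 0.209 times VLDL (0.150 to 0.300) and 0.383 times chylomicrons (0.264 to 0.580). These intervals leave out the error of the size factors. They also leave out any bias from setting the factors on miRNAs that had to be read in LDL, which held 59 miRNA reads. Of 9 ratios of its 3 named members, 7 lay below 1 with their interval after scaling and 1 before. Scaling moves all miRNA ratios of a pair of libraries by the same factor. These values therefore place the family against the 20 miRNAs that set the factor. Those include every form of the family except miR-302c-5p, so the family is partly measured against itself. After scaling miR-302b-3p held 1 against LDL and chylomicrons. It was grouped as a family after its values were seen. miR-302a-5p, miR-302d-3p and miR-302b-3p were among the 5 most abundant miRNAs of LDL, at 48.9, 39.1 and 39.1 RPM.

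More miRNAs were read in HDL (271) than in chylomicrons (66), VLDL (49) or LDL (30), but thinned to the depth of LDL, HDL was expected to show 97.4 (SD 5.15), which argues against depth as the whole cause. A candidate explanation for the HDL excess of miRNA reads is one shared miRNA profile, diluted by other RNA in the other libraries. Chi-square statistics of read counts against HDL gave Monte Carlo p = 0.0001 for each library, the smallest that 10000 resamples can give. On reads without the miR-302 family and the most deviant miRNA, chi-square tests gave p = 0.0002 for chylomicrons, p = 0.0003 for VLDL and p = 0.0092 for LDL, and for LDL p = 0.0002 on miRNAs with at least 10 HDL reads. These tests set single libraries against counting noise alone, without the noise of preparation, so dilution, a distinct profile of the carrier and preparation cannot be told apart in any of the 3 libraries.

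Y RNA reads were 8.69 times higher in HDL than in LDL after summing all Y RNA rows, which argues against division of reads among RNY4 pseudogenes as the source of the difference. The chylomicron to HDL ratio was 0.931 for Y RNA (0.893 to 0.970) and 0.220 for miRNA (0.195 to 0.247). One dilution of all small RNA would give equal ratios, but these intervals cover counting error of single libraries only. Dilution, preparation and a difference between carriers in the Y RNA they hold therefore cannot be told apart, and the last was not tested.

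Protein-coding rows held near-equal shares in all 4 libraries, with RPM related to transcript length (Spearman 0.477 to 0.580 across genes). One explanation is that fragments are spread over annotated exons without regard to mRNA abundance. Ribosomal protein genes, which are highly expressed in most cells, had a median RPM per kb at percentile 9.1 of random gene sets in HDL. The percentile was 6.2 in LDL, 3.3 in chylomicrons and 1.4 in VLDL, so on this measure the list did not stand above random sets. RPM per kb divided the protein-coding row by the longest transcript of any type. Where that transcript is of another type, its reads lie in another row, which lowers the value. An even spread does not account for the VLDL value below the random range. Reads divided with pseudogenes may lower these genes, which was not measured and also limits this test. mRNA of red cells and platelets as the main source was argued against, since neither list passed percentile 68.7 in any library. HBA2 stood at 6.42 RPM and PPBP at 0.651 RPM in HDL. The limit of transcript length applies to these lists as well.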
